A study of Mus musculus with 63 samples.

How the data were processed

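RNA was measured in cells of mouse hearts from the Ki67TagRFP strain, in which a red fluorescent protein (RFP) reports Ki67, a nuclear protein of cycling cells, and in cells of unmarked hearts. The series held 63 samples, 9 of them bulk libraries and 54 single-cell libraries. The bulk libraries came from sorted RFP-positive cells of hearts 3, 7 and 14 days after myocardial infarction (MI), of hearts 14 days after sham surgery and of neonatal hearts. The single-cell libraries came from plates of hearts 14 days after MI, ischaemia/reperfusion (I/R) or sham surgery, of unoperated adults and of neonates. Some plates held RFP-positive or RFP-negative cells, with no label that ties a well to its gate, and others held living cells sorted without RFP. The heart region was the infarct, the remote area, the apex of sham hearts, the ventricles (unoperated letters G to K) or not stated beyond the heart (P, Q, R, T, U, Y and Z), so adult and neonatal groups mix the last kinds of label. Each sample was assigned to its group from its title, source name and characteristics. Titles of letters T and Y name the wild type while genotype and source name give Ki67TagRFP, and the title of letter C points to the apex while its source name gives the remote area; source names were followed.

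Per the labels' protocols, RNA was amplified with CEL-Seq, which reads the 3' ends of polyadenylated transcripts, and sequenced on a NextSeq500 as 75 bp paired reads. Cells of the adult bulk libraries were sorted into Trizol for RNA extraction. The labels of the neonatal bulk libraries describe the plate protocol and name another barcode set. Single cells were sorted into 384-well plates that held primers with 24 bp of poly-T, a random molecular identifier (UMI) of 4 bp and a cell barcode, together with ERCC spike-in RNA. The submitters' processing notes name BWA 0.6.2-r126 and the mouse genome build mm10; the annotation and the counting program are not given in the sources used here, nor is whether counting used strand. Per the labels, the barcode file of letters A to K was that of CEL-Seq and that of letters L to Z that of CEL-Seq2; CEL-Seq plates were split over up to 4 libraries of 96 wells, CEL-Seq2 plates gave 1 library of 384 wells.

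The deposited bulk values were whole-number counts of identifiers per gene. In the adult bulk libraries no count exceeded 256, the number of different identifiers that 4 bases allow, so counts of abundant genes there are compressed; the neonatal libraries reached 10388 and show no such ceiling. The 7 adult bulk files were identical to the columns of the table of the whole series. The deposited single-cell values were estimated counts that need not be whole: each equalled a number of distinct identifiers corrected for collisions, with 256 possible identifiers in CEL-Seq and 4096, as 6 bases would give, in CEL-Seq2, although the labels state 4 bp for every plate. Of 106969536 values, 3 lay off these grids by more than 0.001 of the value. No column of per-sample values was left unmapped.

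ERCC spike-ins and mitochondrially encoded genes were left out of totals and tests, which left 20409 genes in the single-cell libraries. A well was kept as a cell at 1000 or more transcripts, which kept 1981 of 9504 wells; minimums of 500 and 2000 kept 2430 and 1601. Wells were sorted as single cells, so no doublet caller was run. Values were scaled to 5000 transcripts per cell and log-transformed, the 1313 genes among the 3000 most variable in both chemistries (Rn45s, Gm20594, Malat1, Kcnq1ot1 and Lars2 kept out of them) were scaled within each chemistry, and cells were clustered on 25 principal components, 15 neighbours and Leiden resolution 1 (alternatives 0.5 and 1.5). Clusters were named from 16 marker lists fixed before the data were examined. A name needed 3 markers seen in 25% of the cells, a mean marker difference of 0.5 from all other cells, no second list at 0.5 of the first or more, and no more markers of another class than of its own among the top 10 genes by fold. Those naming thresholds were set after the clusters had been seen and before any test. Cell classes are therefore rebuilt names, written below without "-like" in every sentence.

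Counts of the cells of a class were summed per plate letter and rounded to whole numbers; the letter was the replicate, never the cell. The labels do not say that letters or bulk libraries of a group came from separate animals, so p-values measure the spread between these samples, which may be technical. The design, the lists, the rule for named genes and the first set of alternatives were fixed before the data were examined. The plan asked for 20 cells of a class per letter. For fibroblasts that minimum left too few letters for any planned fit, so 5 cells were used for all classes, a choice made from cell numbers alone before any test. For I/R endothelial cells and both macrophage comparisons the planned fit was possible, and for macrophages after MI it gave 183 genes in place of 0; the planned minimum is given wherever a fit could be made, and a minimum of 10 was added. At 5 cells, MI endothelial cells (0 letters), neonatal cells named endothelial (0 letters) and cardiomyocytes (1 letter on each side) could not be tested.

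Summed counts and bulk counts were tested with edgeR's quasi-likelihood test (edgeR 4.0.16 in R 4.3.3) after TMM scaling, with Benjamini-Hochberg adjustment and a threshold of 0.05. Genes with at least 10 counts in at least 3 letters or libraries were tested. All groups entered 1 fit per cell class, with chemistry as a covariate, so that groups of 1 to 6 letters shared an estimate of spread. For neonates against adults the contrast was the mean of the living and RFP neonatal letters against the mean of the living and RFP adult letters. The bulk fit held the 7 adult libraries, or all 9 where neonates were compared. Standard errors of log2 fold changes were taken from the fold change and the F statistic. DESeq2 1.42.0 was the other tool. Where every letter of 1 side had no count, the fold is a bound against a floor of 3 counts over the group.

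The rule for named genes, fixed beforehand, took the 12 largest rises and 12 largest falls per single-cell comparison (8 and 8 in bulk) among genes that passed, were at or above the median abundance and did not overlap between groups, up to 4 members of each of 18 fixed lists with the smallest p, and always Mki67 and Fstl1. The text gives most of the largest changes, Mki67 and Fstl1 where tested, and part of the list members; some genes outside the rule are also named. The lists were mitotic cycle, DNA replication, collagens and matrix, activated fibroblast, scar late fibroblast, resting fibroblast, interferon response, immediate early and dissociation genes, inflammatory cytokines and chemokines, resident macrophage, lipid and repair macrophage, MHC class II, angiogenic endothelium, capillary endothelium, glycolysis, oxidative phosphorylation, sarcomere and fetal growth programme. They were tested with camera (limma 3.58.1) at a preset correlation of 0.01, on log2 CPM with a prior count of 2. Of 221 list tests, 71 passed and 10 of these also passed with an estimated correlation; that second adjusted p stands beside each call that did not. Gene positions are those of GENCODE M21 on GRCm38 (mm10), for the 276 of 280 named genes whose symbol and chromosome matched; reads were counted per gene, so exons, introns and UTRs cannot be separated.

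Class shares per letter were compared between infarct letters (MI and I/R together) and sham apex letters with a 2-sided exact permutation test over 8 classes. For cycling cells, each cell was thinned to 1000 transcripts and counted as cycling at 5 or more transcripts of the mitotic cycle list. Shares carry exact binomial intervals and sums of counts exact Poisson intervals at 95%, which cover counting error only; where a share is 0, the limit given is that of 3 cells of the total. Python 3.11.15, scanpy 1.11.5, leidenalg 0.10.2, scipy 1.17.1 and statsmodels 0.14.6 were used. Each test was tested on simulated data first. With 200 genes changed, the share of 4-fold changes recovered was 7% for fibroblasts after MI against sham (5604 genes), 0% after I/R against sham, after I/R against MI and in infarct against remote area, 18% in neonates against adults and 15% in sham against adults. It was 21% for endothelial cells (5886 genes), 1% and 7% for macrophages after MI and I/R (6788 genes), 53%, 65% and 52% for the bulk comparisons of 3 with 14, 7 with 14 and 3 with 7 days (2038 genes), 0% for bulk MI against sham and 72% for bulk neonates against 14 days (4680 genes). Alternatives were RLE size factors, DESeq2, other count filters, other cell minimums, no chemistry covariate, CEL-Seq2 letters only, only the groups compared, cycling cells left out, a replicate block where numbers were shared, corrections for the identifier ceiling, Rn45s and 4 other abundant genes left out, the bulk sham library left out of the fit, and each letter or library left out in turn.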

Results

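RNA was counted per gene in cells of mouse hearts, with the Ki67TagRFP reporter strain used to sort cells that had made Ki67, a nuclear protein of cycling cells. The series describes proliferating heart cells after injury, in the unoperated adult and in the neonate. Of 63 libraries, 9 were bulk libraries of RFP-positive cells: 2 each at 3, 7 and 14 days after myocardial infarction (MI), 1 at 14 days after sham surgery and 2 from neonates. The total count was 32069 and 117434 at 3 days, 42695 and 164559 at 7 days, 57558 and 117643 at 14 days, 4765 after sham and 899677 and 905116 in neonates. The other 54 libraries held single cells from 26 plates, each named by a letter. Cells sorted as RFP-positive or RFP-negative came from the MI infarct (3 letters, 184 cells), the MI remote area (2, 175), the infarct after ischaemia/reperfusion (I/R; 3, 229), the sham apex (4, 280), the sham remote area (1, 88), unoperated adults (6, 337) and neonates (1, 292). Living cells sorted without the reporter came from adults (4 letters, 179 cells; for letters T and Y title and genotype disagree on the strain), a neonatal plate (1, 27) and an infarct 14 days after MI (1, 190). Transcripts summed over the wells of a letter ranged from 38917 to 9156295, and the median per cell from 1427 to 26764. Which gate a well came from is not given in the sources used here, so RFP-positive and RFP-negative cells were pooled.

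Clustering and marker genes gave 533 endothelial cells, 371 macrophages, 302 fibroblasts, 292 cardiomyocytes, 124 smooth muscle cells, 30 B lymphocytes and 19 pericytes, with 310 cells left unnamed. In infarct letters (MI and I/R together), macrophages made up 35.0% ± 25.2 of the cells (SD, n = 6), against 16.2% ± 21.7 in the sham apex (n = 4). Fibroblasts made up 21.3% ± 19.7 against 5.72% ± 5.21. Endothelial cells, which line vessels, made up 9.62% ± 10.5 in infarcts and 51.1% ± 19.5 in sham hearts. In a 2-sided exact permutation test over 210 splits of the letters, the endothelial difference had p = 0.0095, and p = 0.0762 after Benjamini-Hochberg adjustment over 8 classes. Adjusted p was 0.419 for fibroblasts and 0.476 for macrophages, and smooth muscle cells made up 15.6% ± 26.0 and 16.1% ± 16.2 (adjusted p = 0.957). Unnamed cells made up 17.5% ± 5.58 of infarct cells and 9.21% ± 8.06 of sham cells (adjusted p = 0.419). The largest unnamed group, cluster 3, held 16.3% of MI infarct cells, 3.49% of I/R cells and 3.57% of sham apex cells. Of these MI cells 26 of 30 came from letter E, and without it the cluster held 4 of 63. Cluster 7 held 22.2% and 19.5% of the living and RFP neonatal cells, 6 of 27 and 57 of 292. Its best list was endothelial (difference 0.69), but its top genes held more markers of another class. At resolution 1.5 a cluster of 53 cells, 90.6% from the RFP neonatal letter, was named endothelial. Neonatal cells named endothelial, 0 of 27 and 2 of 292, may therefore be an undercount. Cluster 11 held 7.72% of unoperated adult cells, 20 of 26 from letter Z. Cluster 17 held 5.68% of I/R cells, all 13 from letter S, and 4.15% of unoperated adult cells, and cluster 20 held 3.49% of I/R cells, all 8 from letter X, and 2.5% of sham apex cells, all 7 from letter W. Without MI replicate 3 the fibroblast difference of 15.539 points became 8.363, and without sham replicate 4 the macrophage difference of 18.812 became 28.891. The macrophage difference was 7.393 in CEL-Seq2 letters, and the fibroblast difference 6.456 in letters with at least 20 cells, an alternative chosen after seeing the data. The plate gates were not mapped, so these shares describe sorted cells and not the tissue.

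**Figure D1:**
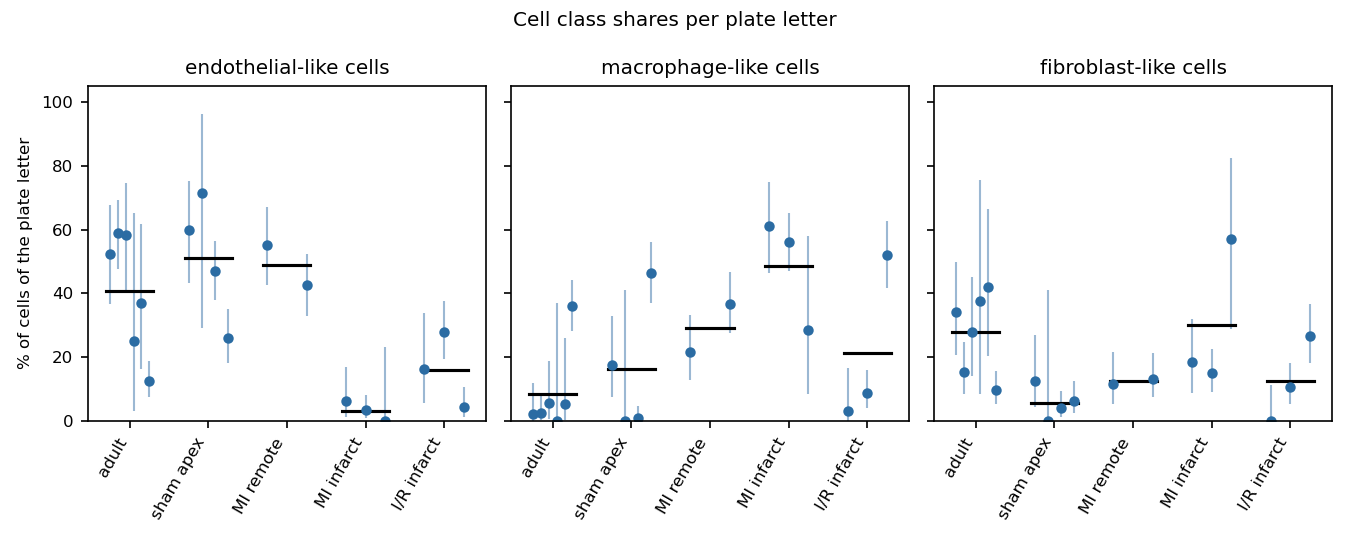
Percent of cells per class in each plate letter for endothelial cells, macrophages and fibroblasts by group, with exact binomial 95% intervals as thin lines and bars at the group mean. Endothelial cells averaged 9.62% in the 6 infarct letters and 51.1% in the 4 sham letters.

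Infarct fibroblasts were compared with sham fibroblasts 14 days after MI to ask what the cells of the scar express. Col1a1, Fn1 and Lox rose in fibroblasts of the infarct, and Smoc2 fell. Col1a1, the main chain of type I collagen (chr11:94936224-94953042), averaged 10960 ± 6351 CPM, the TMM-scaled count (SD, n = 3) in MI letters and 2448 ± 1117 in sham letters (n = 3), a log2 difference of 2.38 ± 0.45 (SE; adjusted p = 0.0349). Fn1, which encodes fibronectin (chr1:71585520-71653200), rose from 458 ± 120 to 4252 ± 2071 CPM (log2 3.74 ± 0.78, adjusted p = 0.0380). Lox, an enzyme that crosslinks collagen (chr18:52516067-52529867), rose from 79.5 ± 1.01 to 769 ± 485 CPM (log2 3.95 ± 0.80, adjusted p = 0.0365). Smoc2, a matrix protein of resting fibroblasts (chr17:14279506-14404790), fell from 1561 ± 246 to 446 ± 171 CPM (log2 -2.35 ± 0.47, adjusted p = 0.0365).

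Of 5604 genes tested with edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment, 10 passed, of which 8 rose and 2 fell. Mdk, a heparin-binding growth factor of the fetal growth programme (chr2:91929805-91932297), rose by 4.95 ± 0.76 (adjusted p = 0.00332). Palld, which organises actin bundles (chr8:61511433-61902690), rose by 4.31 ± 0.88, and Marcksl1 and 1500015O10Rik, at chr4:129513581-129515985 and chr1:43730602-43742578, also rose (adjusted p = 0.0479 each). Runx1, a transcription factor (chr16:92601466-92826149), had 44 counts in MI and 1 in sham fibroblasts, a ratio of 26.1 (95% interval 4.45 to 1050; adjusted p = 0.0365). Gsta3, a glutathione transferase (chr1:21240589-21265661), fell by 3.96 ± 0.81. In the activated fibroblast list, 1 of 22 measured members rose; adjusted over the list alone 10 rose and 1 fell, and the list as a whole was higher (camera adjusted p = 6.03e-12, and adjusted p = 0.00135 with an estimated correlation). In the scar late list, made of genes of mature scar, none of 8 passed, 7 rose adjusted over the list alone, and the list was higher (camera adjusted p = 4.11e-07, and adjusted p = 0.0048 with an estimated correlation). Comp, a cartilage and tendon matrix protein of that list, averaged 1195 ± 1220 CPM in MI and was not counted in sham, at least 96.9-fold higher (adjusted p = 0.0932). In the resting fibroblast list, 1 of 19 fell, 1 rose and 6 fell adjusted over the list alone, and the list was lower (camera adjusted p = 2.65e-05, and adjusted p = 0.0048 with an estimated correlation). Of 29 collagen and matrix genes 3 rose, 9 adjusted over the list alone (camera adjusted p = 4.01e-05, and adjusted p = 0.156 with an estimated correlation). Of 6 fetal growth genes 1 rose, 2 adjusted over the list alone (camera adjusted p = 0.0012, and adjusted p = 0.0155 with an estimated correlation). The lipid and repair macrophage list, which also holds Fn1, was higher (camera adjusted p = 0.0251, and adjusted p = 0.156 with an estimated correlation). Fstl1, a secreted glycoprotein of fibroblasts (chr16:37776873-37836514), measured 6287 ± 1350 against 4308 ± 1365 CPM (log2 0.75 ± 0.36, adjusted p = 0.616). The mitotic cycle list was lower (camera adjusted p = 1.02e-06, and adjusted p = 0.471 with an estimated correlation), with Mki67 (chr7:135689784-135716361) at 1 count in MI and 403 in sham fibroblasts, nearly all from sham replicate 3 (adjusted p = 0.162). Cluster 9 held 30 of 35 MI fibroblasts and cluster 10 held 14 of 17 sham fibroblasts. The 4 endothelial markers measured in these sums had a median log2 difference of -2.742 (-5.447 to 0.348), and none passed.

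DESeq2 called 45 genes, 29 higher and 16 lower, all 10 among them. The count was 2 without the chemistry covariate, 1 with only the groups compared and 1 with cycling cells left out, each among the 10. The count was 2, 1 and 18 without MI replicates 1, 2 and 3, and 4, 0 and 1 without sham replicates 1, 3 and 4. In that order 2, 1 and 4, and 3, 0 and 1 of these were among the 10. The sums held 5 to 18 fibroblasts per letter. The median log2 difference of the activated fibroblast list, with a pseudocount of 20 CPM, was 1.91 within CEL-Seq and 0.84 within CEL-Seq2.

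**Figure D2:**
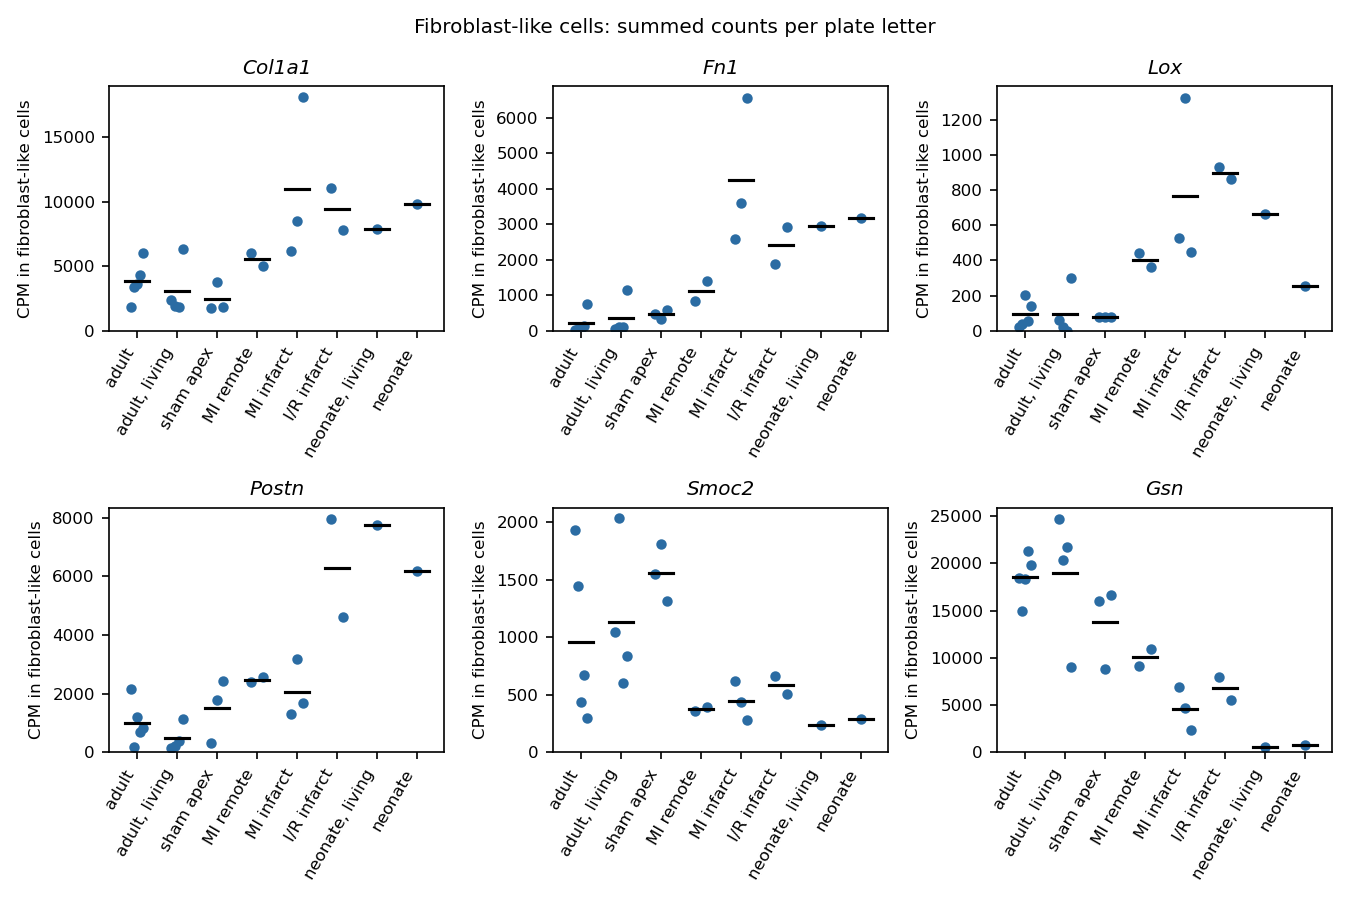
CPM (linear axis) of 6 genes in fibroblast sums, with 1 point per plate letter and a bar at the group mean. Col1a1 averaged 10960 CPM in the 3 MI letters and 2448 CPM in the 3 sham letters; Smoc2 averaged 446 and 1561 CPM.

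After I/R, fibroblasts were compared with the same sham letters to see the response to a reperfused infarct. Collagen type I and crosslinking genes again had higher values than in sham, without passing the test. Lox averaged 899 ± 46.6 CPM (SD, n = 2) against 79.5 ± 1.01 (n = 3; log2 3.26 ± 0.79, adjusted p = 0.589) and Col1a1 9435 ± 2296 CPM (log2 1.67 ± 0.48, adjusted p = 0.606). Cthrc1, a secreted protein of activated fibroblasts, averaged 633 ± 274 against 43.3 CPM, and Cilp, a matrix protein of cartilage and scar, 1665 ± 1084 against 122 ± 203 (adjusted p = 0.618 each). Comp was at least 80.9-fold higher (adjusted p = 0.345) and Fstl1 averaged 8417 ± 857 CPM (log2 0.80 ± 0.40, adjusted p = 0.999). The activated fibroblast list was higher, with 11 members past the threshold adjusted over the list alone (camera adjusted p = 4.61e-14, and adjusted p = 0.000621 with an estimated correlation). The scar late list was higher with 4 (camera adjusted p = 2.45e-06, and adjusted p = 0.013 with an estimated correlation). The collagen and matrix list had 2 (camera adjusted p = 2.45e-06, and adjusted p = 0.135 with an estimated correlation). The fetal growth list was higher (camera adjusted p = 0.00648, and adjusted p = 0.0508 with an estimated correlation), as was the resident macrophage list (camera adjusted p = 0.015, and adjusted p = 0.225 with an estimated correlation). The mitotic cycle list was lower (camera adjusted p = 9.76e-10, and adjusted p = 0.332 with an estimated correlation), as was DNA replication (camera adjusted p = 0.00209, and adjusted p = 0.179 with an estimated correlation). Mki67 differed by -4.2174 (adjusted p = 0.798), and by 1.0879 without sham replicate 3 (adjusted p = 0.999). Cluster 9 held 23 of 36 I/R fibroblasts and cluster 10 held 14 of 17 sham ones, and the 4 endothelial markers had a median log2 difference of 1.601 (-0.384 to 2.593). No gene passed edgeR's test, with 231 at an unadjusted p under 0.05, and DESeq2 called 0.

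Further comparisons placed the MI infarct beside the I/R infarct and the remote area of MI hearts. In I/R fibroblasts (n = 2), values of Fn1 were lower than in MI fibroblasts (n = 3; log2 -2.08) and those of Scara5, a ferritin receptor of resting fibroblasts, higher (log2 2.74; adjusted p = 1 each). The resting fibroblast list was higher after I/R (camera adjusted p = 0.00352, and adjusted p = 0.0554 with an estimated correlation). So was the capillary endothelium list, which includes the fatty acid transporter Cd36 (camera adjusted p = 0.00483, and adjusted p = 0.157 with an estimated correlation). The 4 endothelial markers measured were all higher there, at a median log2 difference of 3.636 (0.68 to 8.04), and none passed. Against the remote area (n = 2), infarct fibroblasts had 3457 ± 2462 CPM of Sfrp2, a Wnt modulator of the scar late list, against 176 ± 67.4 (log2 4.20 ± 1.04). They had 1320 ± 199 CPM of the basement membrane collagen gene Col15a1 against 3237 ± 846 (log2 -1.25). Neither passed (adjusted p = 1 each). The 4 endothelial markers were all lower in the infarct, at a median of -2.067 (-4.61 to -0.409), and none passed. The immediate early and dissociation list was higher in the infarct (camera adjusted p = 0.00234, and adjusted p = 0.538 with an estimated correlation). Fstl1 differed by 0.05 ± 0.42 between I/R and MI and by -0.11 ± 0.40 between infarct and remote area. Mki67 had 51 counts in I/R and 1 in MI fibroblasts, a ratio of 39.7 (95% interval 6.8 to 1600; adjusted p = 1). That interval covers counting error only and not the spread between letters. In fibroblasts of the remote area Mki67 had 3 counts (adjusted p = 1). No gene passed edgeR's test in either comparison, with 197 and 111 at an unadjusted p under 0.05, and DESeq2 called 1 and 0. For infarct against remote area the count was 20 with only the groups compared, 28 with a replicate block over letters A, B, E and F, and 25 in these letters without the block, the last chosen after seeing the data.

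Neonatal fibroblasts, from hearts that still grow by cell division, were compared with fibroblasts of unoperated adults. Igf2 and Postn rose in neonatal fibroblasts, and Gsn and C3 fell. Igf2, an imprinted growth factor (chr7:142650766-142666816), averaged 1646 ± 1248 CPM (SD, n = 2) against 17.9 ± 32.7 (n = 9; log2 6.49 ± 0.74, adjusted p = 9.6e-06). Postn, a matrix protein of growing and injured connective tissue (chr3:54361109-54391037), averaged 6966 ± 1122 against 767 ± 654 CPM (log2 3.40 ± 0.54, adjusted p = 0.000362). Gsn, which severs actin and marks resting fibroblasts (chr2:35256380-35307892), fell from 18770 ± 4521 to 673 ± 180 CPM (log2 -4.85 ± 0.55, adjusted p = 9.6e-06). The complement protein gene C3 (chr17:57203970-57228136) fell from 1936 ± 1228 to 20.5 ± 29.1 CPM (log2 -8.14 ± 1.25, adjusted p = 0.000263).

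In this comparison Mki67 averaged 256.2 ± 102.4 against 46.68 ± 110.1 CPM (log2 3.252 ± 1.104, adjusted p = 0.105). Altogether 223 genes passed edgeR's test, of which 96 rose and 127 fell, and DESeq2 called 278, of which 60 rose and 218 fell. Fn1 (log2 3.98 ± 0.57), Nrep, a neuronal regeneration related protein (4.18 ± 0.60), the pleiotrophin gene Ptn (4.22) and Mdk (2.70) rose. Cthrc1 (4.54) and the elastin gene Eln (3.27) rose, and Fstl1 rose from 2835 ± 943 to 6220 ± 489 CPM (log2 1.20 ± 0.31, adjusted p = 0.0268). C1s1, a complement protease, was at least 34.6-fold lower, Cxcl14, a chemokine, at least 126.4-fold lower and the MHC class I gene H2-D1 at least 24.2-fold lower, each without a count in neonates. Among the largest rises were also the actin gene Acta2 (log2 3.128), Kctd12 (2.885), Tagln, a smooth muscle protein (2.626), Fscn1, which bundles actin (2.467), Itm2a (2.293), the microfibril gene Mfap2 (2.254) and Lhfpl2 (2.199). Among the largest falls were Pi16, a marker of resting fibroblasts (log2 -6.575), and Gsta3 and Wisp2, at least 23.1-fold and 16.4-fold lower without a count in neonates. Others had 1 or 2 neonatal counts: Ly6a (adult to neonate ratio 121, 95% interval 33.2 to 1000), Hsd11b1 (115, 20.4 to 4570), Xdh (55.9, 9.76 to 2230), Itgbl1 (52.5, 9.16 to 2100) and Cyp1b1 (49.9, 8.68 to 2000). Of 27 mitotic cycle genes 12 rose, 25 adjusted over the list alone, among them Top2a, Cdk1 and Ccnb1 (log2 4.81, 5.57 and 5.34; camera adjusted p = 2.98e-14, and adjusted p = 0.174 with an estimated correlation). Of 9 DNA replication genes 3 rose, 7 adjusted over the list alone, among them Rrm2 (log2 4.27; camera adjusted p = 2.02e-06, and adjusted p = 0.0359 with an estimated correlation). Of 6 fetal growth genes 5 rose, 6 adjusted over the list alone (camera adjusted p = 1.91e-12, and adjusted p = 6.65e-05 with an estimated correlation). Of 19 resting fibroblast genes 11 fell, 16 adjusted over the list alone (camera adjusted p = 7.69e-25, and adjusted p = 3.71e-06 with an estimated correlation). In the activated fibroblast list 7 of 22 rose and 1 fell, 8 and 2 adjusted over the list alone, and the list did not pass as a whole (camera adjusted p = 0.0661).

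Of 29 collagen and matrix genes 7 rose, such as Col3a1 (log2 1.49), and 2 fell, such as Col8a1 (log2 -3.63; 11 and 4 adjusted over the list alone; camera adjusted p = 0.0444, and adjusted p = 0.425 with an estimated correlation). The scar late list was lower, with 2 of 8 genes down and 4 adjusted over the list alone (camera adjusted p = 0.00426, and adjusted p = 0.0717 with an estimated correlation). Interferon genes were lower, with 2 of 7 down, such as Ifi27l2a (log2 -4.03), and 6 adjusted over the list alone (camera adjusted p = 1.6e-05, and adjusted p = 0.0608 with an estimated correlation). Of 4 resident macrophage genes, which fibroblasts also express, 2 fell (camera adjusted p = 0.000315, and adjusted p = 0.0608 with an estimated correlation). The lipid and repair list was lower (camera adjusted p = 0.0218, and adjusted p = 0.105 with an estimated correlation), as was the MHC class II list (camera adjusted p = 0.0194, and adjusted p = 0.268 with an estimated correlation). Oxidative phosphorylation genes were higher, with Cycs (log2 1.67) up (camera adjusted p = 0.00308, and adjusted p = 0.0717 with an estimated correlation). All 4 measured sarcomere genes rose, with Actc1, the cardiac actin, at 1606 ± 2047 against 41.0 ± 59.4 CPM (log2 4.69 ± 0.60, adjusted p = 7.88e-05). The list was higher (camera adjusted p = 1.11e-09, and adjusted p = 0.00226 with an estimated correlation), 4 genes also adjusted over the list alone. Cardiomyocyte markers moved with the neonatal group, as 4 of 4 rose, and 2 of 4 smooth muscle markers rose. The sarcomere list summed to 7955.1 CPM in the fibroblasts of the RFP neonatal plate, which was mostly cardiomyocytes, and 942.9 in those of the living neonatal plate. With the living neonatal letter against living adults the 4 sarcomere genes did not pass (Actc1 at log2 0.69, adjusted p = 0.912). In alternatives chosen after seeing the data, the count was 43 (28 rose, 15 fell, 36 shared) with the living letter against living adults, and 20 (10 and 10, all shared) with the RFP letter against RFP adults, where Top2a was at log2 -0.10. Cluster 9 held all 14 and 20 of 21 neonatal fibroblasts, and cluster 10 held 52 of 63 and 47 of 59 adult ones.

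Sham fibroblasts, from the apex, were compared with those of unoperated adults, from the ventricles or from hearts without a stated region. Surgery and region therefore cannot be told apart here. The scar late list was lower in sham fibroblasts, with 6 genes past the threshold adjusted over the list alone (camera adjusted p = 5.02e-05, and adjusted p = 0.0555 with an estimated correlation). Cluster 8, with Prg4 and Fmod among its top genes, held 8 of 63 adult and 0 of 17 sham fibroblasts. Prg4, the joint lubricant lubricin, was at least 51.7-fold lower, without a count in sham (adjusted p = 0.132). Hspa1b, a heat shock protein, averaged 211 ± 84.9 CPM (SD, n = 3) against 1487 ± 736 (n = 5; log2 -2.77, adjusted p = 0.864), and its list of immediate early and dissociation genes was lower (camera adjusted p = 5.76e-07, and adjusted p = 0.336 with an estimated correlation). The mitotic cycle list was higher (camera adjusted p = 0.00099, and adjusted p = 0.813 with an estimated correlation). Mki67 differed by 3.1536 (adjusted p = 0.94), and by -1.84 without sham replicate 3 (adjusted p = 0.998). Fstl1 averaged 4308 ± 1365 against 2966 ± 972.8 CPM (log2 0.489, adjusted p = 0.94). In the other direction, the activated and resting fibroblast lists were lower (camera adjusted p = 0.0266 and 0.0498, and adjusted p = 0.279 each with an estimated correlation). No gene passed edgeR's test, with 251 at an unadjusted p under 0.05, and DESeq2 called 2.

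Endothelial cells of I/R infarcts were compared with those of sham hearts, and no gene passed. Mki67 averaged 588 ± 831 CPM (SD, n = 2) against 1040 ± 979 (n = 4; log2 -0.77 ± 0.90, adjusted p = 0.998), Cd36 5069 ± 275 against 3781 ± 1063 and Fstl1 346.1 ± 135.6 against 188.3 ± 132.6 (log2 0.671, adjusted p = 0.998). The 3 macrophage markers in these sums were all lower, at a median of -3.483 (-6.572 to -0.069), and none passed. Without I/R replicate 1 Mki67 differed by 0.127, and with the planned 20 cells by 0.7224 (adjusted p = 1 each). The mitotic cycle list was lower after I/R (camera adjusted p = 4.01e-11, and adjusted p = 0.781 with an estimated correlation), with the kinetochore gene Nuf2 at log2 -1.97. The DNA replication list was lower too (camera adjusted p = 0.0079, and adjusted p = 0.781 with an estimated correlation). The collagen list was higher (camera adjusted p = 0.0178, and adjusted p = 0.815 with an estimated correlation), as was the activated fibroblast list (camera adjusted p = 0.0273, and adjusted p = 0.781 with an estimated correlation). The quasi-likelihood test of edgeR called 0 of 5886 genes, with 120 at an unadjusted p under 0.05, and DESeq2 called 0. With the planned 20 cells per letter, 1 letter against 3, the count was 0, and the lone letter is assumed to vary like the others.

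Macrophages of MI infarcts were compared with those of sham hearts. Sham apex was the only macrophage group with letters of both chemistries, D and W. Both MI letters were CEL-Seq, so with chemistry in the fit the folds and p-values rest on sham letter D alone (7 macrophages). Means, SDs and counts use sham D and W, mixing chemistries. Ccl12, a monocyte-attracting chemokine, averaged 85.4 ± 66.0 CPM (SD, n = 2) in MI and 729 ± 107 (n = 2) in sham (log2 -3.36 ± 0.67, adjusted p = 0.315). Cxcl2, which attracts neutrophils, averaged 4696 ± 1009 against 671 ± 159 CPM (log2 2.58, adjusted p = 0.816). Fstl1 averaged 33.92 ± 0.4477 against 17.4 ± 5.327 CPM (log2 0.666, adjusted p = 0.952). Cd163, a haemoglobin receptor of resident macrophages, was at log2 -4.44, and Timd4, which binds dying cells, had 0 counts in MI and 59 in sham (adjusted p = 0.816 each). No gene passed edgeR's test, with 326 at an unadjusted p under 0.05, and DESeq2 called 0; no list passed, the lowest being mitotic cycle (camera adjusted p = 0.0589). The median log2 difference over all 6788 genes was 0.39, and 0.25 with RLE size factors. With the planned 20 cells, 2 letters against 1, edgeR called 183 genes, 80 higher and 103 lower, among them Mki67 with a log2 difference of -1.92 against 0.62 with 5 cells (adjusted p = 0.0179 and 0.935). The lone sham letter, W, is assumed to vary like the others. It was CEL-Seq2 and both MI letters were CEL-Seq, so these calls cannot be told apart from chemistry. The same holds for the count without sham replicate 1. The count was 7 and 1 without MI replicates 1 and 2, and 43 and 0 without sham replicates 1 and 4. Cluster 0 held 96 of 102 MI macrophages and 33 of 60 sham ones, and cluster 2 held 26 of the 60.

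After I/R, macrophages had less Cxcl10, an interferon-induced chemokine (chr5:92346638-92348889), and less Lyve1, a hyaluronan receptor of resident macrophages (chr7:110850607-110863239), than sham macrophages. Both I/R letters were CEL-Seq2, so with chemistry in the fit the folds and p-values rest on sham letter W alone (52 macrophages). Means and SDs use both sham letters, D and W. Cxcl10 averaged 12.9 ± 18.3 CPM (SD, n = 2) against 310 ± 229 (n = 2; log2 -4.35 ± 0.67, adjusted p = 0.0161), and Lyve1 39.1 ± 23.9 against 259 ± 336 (log2 -4.20 ± 0.72, adjusted p = 0.0344). Spp1, which encodes osteopontin (chr5:104435118-104441050), averaged 2607 ± 3647 against 264 ± 286 CPM (log2 5.46 ± 1.40, adjusted p = 0.594), and Fn1 756 ± 159 against 107 ± 88.9 (log2 4.13 ± 1.08, adjusted p = 0.594). Fstl1 averaged 94.62 ± 15.1 against 17.4 ± 5.327 CPM (log2 2.838, adjusted p = 0.623) and Mki67 304.2 ± 74.04 against 145.3 ± 145.6 (log2 0.36, adjusted p = 1). In the resident macrophage list 1 of 13 genes fell, 3 adjusted over the list alone (camera adjusted p = 0.0127, and adjusted p = 0.738 with an estimated correlation). The collagen list was higher, with no gene past the threshold and 3 adjusted over the list alone (camera adjusted p = 0.000578, and adjusted p = 0.758 with an estimated correlation), as was mitotic cycle (camera adjusted p = 0.00406, and adjusted p = 0.882 with an estimated correlation). The 6 fibroblast markers measured had a median log2 difference of 1.171 (-0.166 to 2.466), and the 5 cardiomyocyte markers -2.193 (-3.3 to -0.671), none past the threshold. Cluster 2 held 10 of 59 I/R and 26 of 60 sham macrophages, and cluster 0 held 44 and 33. Cxcl10 and Lyve1 were the whole count in edgeR's test, and DESeq2 called 0. Without sham replicate 4 Lyve1 differed by 0.2632 (adjusted p = 0.983), Cxcl10 no longer passed (adjusted p = 0.748), and with cycling cells left out Cxcl10 differed by -1.3839 (adjusted p = 1). With the planned 20 cells, 1 letter against 1, edgeR called 17 genes, 14 higher and 3 lower, each lone letter assumed to vary like the others. The count was 2 and 0 without sham replicates 1 and 4, and 1 and 0 without I/R replicates 2 and 3. That 1 gene was neither Cxcl10 nor Lyve1.

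Cardiomyocytes were too few for a test, with 185 on the RFP neonatal plate, 92 on the living MI plate and 5 on an adult plate, and no other letter held more than 2. Neonatal cardiomyocytes expressed sarcomere genes at 107400 CPM (exact Poisson 95% interval 107100 to 107600). The 5 cells of the adult plate that clustered with them had 2706 CPM from 25 counts (1751 to 3995), less than the 7955.1 CPM in fibroblasts of the RFP neonatal plate, so their name is in doubt and no age contrast is drawn. Actc1 was at 32290 CPM in neonatal cells (32150 to 32430) and the ventricular light chain Myl2 at 14400 (14310 to 14490). Mitotic cycle genes were counted there too, with Mki67 at 228 CPM (216 to 240), Top2a at 288 (275 to 302) and the cyclin-dependent kinase Cdk1 at 351 (336 to 366).

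Cells counted as cycling, with at least 5 mitotic cycle transcripts among 1000, were compared between groups to ask which cell types divide. Endothelial cells were cycling in 37 of 115 sham cells (32.2%, exact 95% interval 23.8 to 41.5), 10 of 38 I/R cells (26.3%, 13.4 to 43.1) and 11 of 121 unoperated adult cells (9.09%, 4.63 to 15.7). Cluster 1, set apart by cell cycle genes and with 0 endothelial markers among its top 10 genes, held 34, 10 and 13 of these endothelial cells. It was named as a whole at a marker difference of 0.72, and letter O supplied 27.4% of it. Cycling cells of other classes may sit in it, which would raise the endothelial shares and lower those of other classes. That was not tested. Macrophages were cycling in 16 of 58 adult cells (27.6%, 16.7 to 40.9), 8 of 60 sham cells (13.3%, 5.94 to 24.6), 7 of 59 I/R cells (11.9%, 4.91 to 22.9) and 0 of 102 MI cells, which allows a share of up to 2.94%. Most of these macrophages came from single letters, 52 of 58 adult cells from letter Z, 52 of 60 sham cells from W and 49 of 59 I/R cells from X, where 16, 8 and 2 were cycling, so the groups differ by plate as well. Of neonatal cardiomyocytes 56 of 185 were cycling (30.3%, 23.8 to 37.4), and of those on the living MI plate 0 of 92, which allows up to 3.26%. Of fibroblasts, 5 of 21 cells of the RFP neonatal plate were cycling, against 1 of 35 in MI, 1 of 36 in I/R, 2 of 17 in sham and 3 of 63 in adult cells. The share per letter of cycling fibroblasts was 3.30% ± 5.43 in infarcts (SD, n = 5) and 13.3% ± 23.1 in sham (n = 3; 2-sided exact permutation test over 56 splits, p = 0.554). Without sham replicate 3 the difference of -10.03 points became 3.30. Sorting on the reporter sets how many cycling cells reached a plate. Shares on plates sorted without it, such as 3 of 14 fibroblasts of the living neonatal plate or 0 of 75 adult endothelial cells (1 of 76 had too few whole transcripts to thin), which allows up to 4.00%, are therefore not comparable with the rest.

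**Figure D3:**
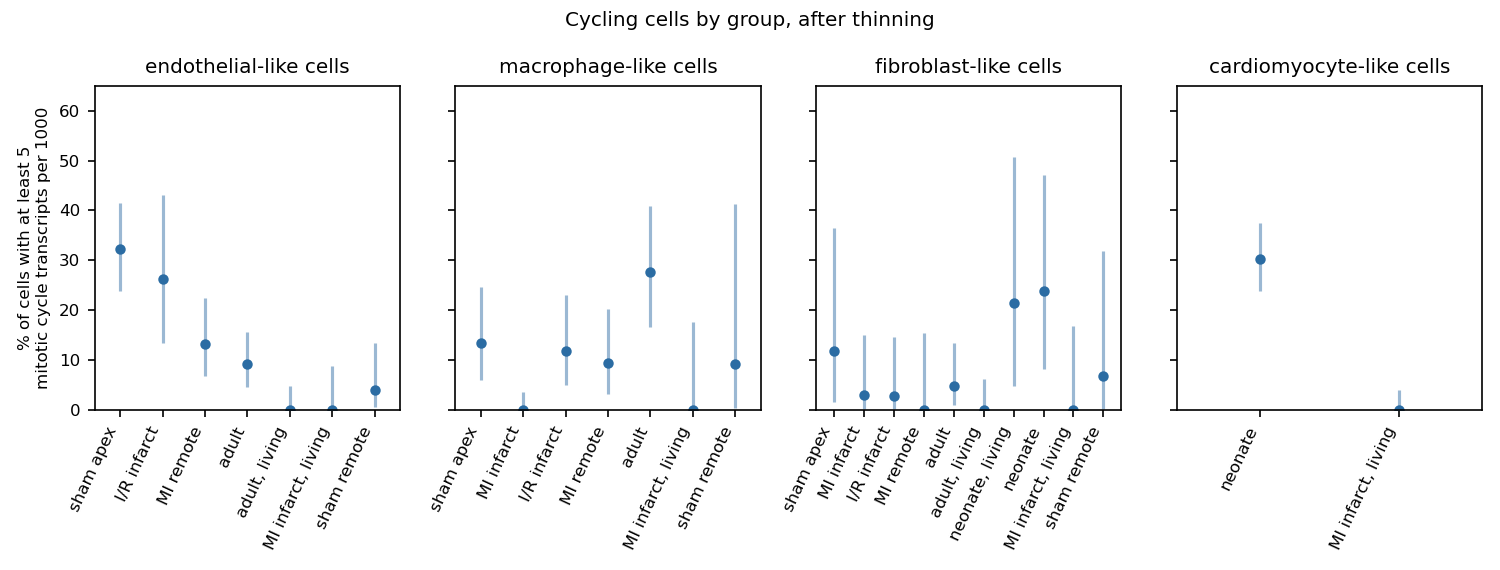
Percent of cells with at least 5 mitotic cycle transcripts among 1000, by cell class and group (points), with exact binomial 95% intervals as lines. Sham endothelial cells were at 32.2%, neonatal cardiomyocytes at 30.3% and MI macrophages at 0 of 102 cells.

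Bulk RFP-positive cells were compared between 3 and 14 days after MI to follow the proliferating cells over time. Spp1, Mrc1 and Arg1 rose at 3 days against 14 days, and Lum and Mmp2 fell. Spp1 rose from 59.8 ± 3.14 CPM at 14 days (SD, n = 2) to 2972 ± 483 at 3 days (n = 2; log2 5.58 ± 0.70, adjusted p = 8.44e-05). Mrc1, a mannose receptor of macrophages (chr2:14229392-14332057), rose from 59.8 ± 3.14 to 1120 ± 2.08 (log2 4.19 ± 0.50, adjusted p = 8.44e-05). Arg1, the arginase of repair macrophages (chr10:24915221-24927484), was at least 73.0-fold higher, without a count at 14 days. Lum, which encodes the collagen-binding lumican (chr10:97565128-97572703), was lower at 3 days, 95.4 ± 62.8 against 1833 ± 1004 CPM (log2 -3.90 ± 0.59, adjusted p = 0.000312), as was the gelatinase gene Mmp2, 140 ± 18.3 against 2057 ± 995 (log2 -3.89 ± 0.49).

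Of 2038 genes 439 passed edgeR's test, 238 higher and 201 lower at 3 days; RLE size factors gave 283 higher and 153 lower and moved the median of all genes from 0.03 to 0.22 log2, and DESeq2 called 190, 142 higher and 48 lower. The chemokine gene Ccl8 was at least 39.8-fold and the clotting factor gene F13a1 at least 38.3-fold higher, and the myeloid transcription factor gene Spi1 (log2 4.26) and the receptor gene Csf1r (log2 3.59) rose. The lipase gene Pla2g7 (log2 3.788), the receptor gene Sirpa (3.752) and the complement receptor gene C3ar1 (3.674) rose, and the matrix-associated Cyr61 (-4.404), Sfrp2 (-3.842) and Prelp (-3.823) fell. Of 9 resident macrophage genes 6 rose (camera adjusted p = 2.58e-05, and adjusted p = 0.343 with an estimated correlation), such as the platelet factor Pf4 (log2 3.70). Of 13 lipid and repair genes 4 rose and 1 fell (camera adjusted p = 0.00333, and adjusted p = 0.343 with an estimated correlation). Of 4 MHC class II genes 3 rose (camera adjusted p = 0.0336, and adjusted p = 0.366 with an estimated correlation). Of 19 collagen and matrix genes 15 fell, among them Eln (log2 -3.46), Bgn (-3.34) and Col4a1 (-2.65; camera adjusted p = 3.27e-09, and adjusted p = 0.343 with an estimated correlation). Of 11 activated fibroblast genes 5 fell, 7 adjusted over the list alone (camera adjusted p = 0.00173, and adjusted p = 0.343 with an estimated correlation). Fstl1 averaged 687 ± 37.3 against 2701 ± 480 CPM (log2 -1.98 ± 0.41, adjusted p = 0.00272), and Postn fell by 2.50. Of 5 resting fibroblast genes 3 fell (camera adjusted p = 0.0246, and adjusted p = 0.343 with an estimated correlation). Adjusted over the list alone, 4 resting fibroblast and 5 lipid and repair genes passed in these directions and the other list counts above were the same. Of 20 immediate early genes 7 fell, also adjusted over the list alone, such as Egr1 (log2 -3.87) and Nr4a1 (-3.00; camera adjusted p = 0.000816, and adjusted p = 0.366 with an estimated correlation). Markers of cell types moved with time, as 8 of 10 macrophage markers rose, and 6 of 7 fibroblast and 4 of 4 endothelial markers fell. The run code in the labels was the same at 3 and 7 days and another at 14 days, so run and time cannot be told apart. The count was 266 and 277 without 14 day replicates 1 and 2, and 288 without 3 day replicate 2.

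**Figure D4:**
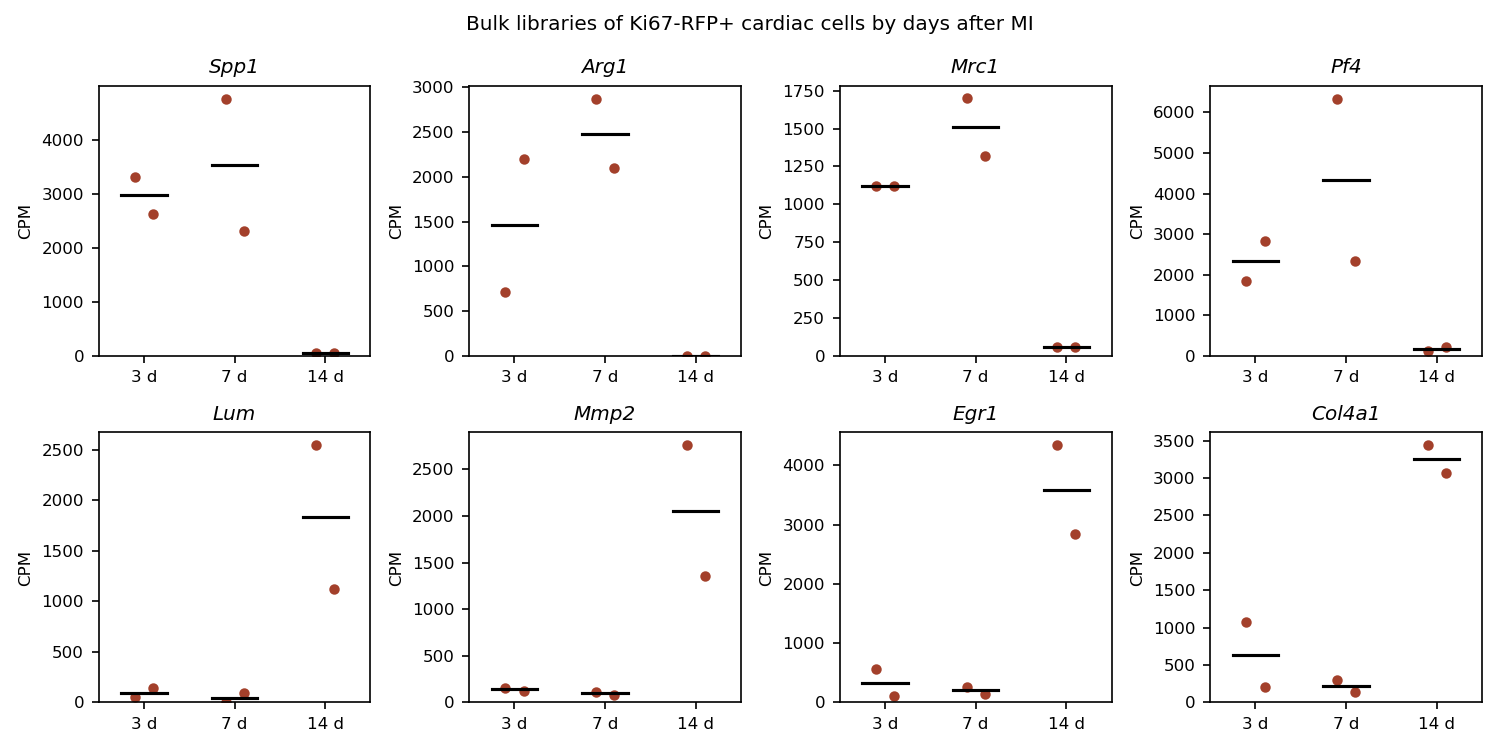
CPM (linear axis) of 8 genes in each bulk library of RFP-positive cells at 3, 7 and 14 days after MI. Spp1 averaged 2972 CPM at 3 days and 59.8 at 14 days, and Lum 95.4 and 1833.

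Arg1 and Spp1 rose at 7 days against 14 days, and Lum and Fstl1 fell. Ccl6, a macrophage chemokine, had 300 counts at 7 days and 3 at 14 days, a ratio of 84.5 (95% interval 28.6 to 412). Arg1 was at least 85.7-fold higher (2480 ± 550 CPM; SD, n = 2), and Spp1 averaged 3534 ± 1728 CPM (log2 5.82 ± 0.70, adjusted p = 4.33e-05). Lum fell by 4.63 ± 0.60, and Fstl1 averaged 313 ± 91.8 CPM (log2 -3.20 ± 0.44, adjusted p = 9.13e-05). Mrc1 (log2 4.591), Pf4 (4.549), Alox5ap, of leukotriene synthesis (4.04), the iron exporter gene Slc40a1 (3.798), Sirpa (3.669) and C3ar1 (3.662) rose. Gadd45b, a stress gene (log2 -4.945), Mmp2 (-4.441), Egr1 (-4.271), the protease inhibitor gene Timp3 (-4.22), Crispld2 (-4.134) and Col4a1 (-4.095) fell. In edgeR's test 552 genes passed, 302 higher and 250 lower. RLE size factors gave 361 higher and 199 lower with the median moved from 0.02 to 0.20, and DESeq2 called 239, 166 higher and 73 lower. Collagen and matrix genes fell in 18 of 19 (camera adjusted p = 1.03e-11, and adjusted p = 0.259 with an estimated correlation). Activated fibroblast genes fell in 9 of 11 (camera adjusted p = 0.000149, and adjusted p = 0.303 with an estimated correlation) and immediate early genes in 11 of 20 (camera adjusted p = 2.77e-05, and adjusted p = 0.303 with an estimated correlation). Resting fibroblast genes fell in 4 of 5 (camera adjusted p = 0.0311, and adjusted p = 0.313 with an estimated correlation) and angiogenic endothelium genes in 3 of 4 (camera adjusted p = 0.0311, and adjusted p = 0.369 with an estimated correlation). Resident macrophage genes rose in 6 of 9 (camera adjusted p = 0.000142, and adjusted p = 0.303 with an estimated correlation). Chemokine genes rose in 4 of 10 with 1 down (camera adjusted p = 0.0456, and adjusted p = 0.303 with an estimated correlation) and lipid and repair genes in 5 of 13 with 1 down (camera adjusted p = 0.00384, and adjusted p = 0.303 with an estimated correlation). MHC class II genes rose in 3 of 4 and glycolysis genes in 3 of 9, such as Pgk1 (log2 2.42, camera adjusted p = 0.0423 each, and adjusted p = 0.369 each with an estimated correlation). Adjusted over the list alone, 12 immediate early genes fell and the other list counts were the same. Macrophage markers rose in 6 of 10, and fibroblast and endothelial markers fell in 6 of 7 and 4 of 4. The count was 357 and 358 without 14 day replicates 1 and 2, and 205 and 226 without 7 day replicates 1 and 2; both comparisons share the 14 day libraries, so their overlap was not counted.

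Between 3 and 7 days, within 1 run code, the collagen and matrix list was higher at 3 days (camera adjusted p = 0.000727, and adjusted p = 0.811 with an estimated correlation). So was the immediate early list (camera adjusted p = 0.00751, and adjusted p = 0.811 with an estimated correlation). Klf4, a transcription factor of that list, averaged 1088 ± 47.0 CPM (SD, n = 2) at 3 days and 429 ± 140 at 7 days (n = 2; log2 1.43 ± 0.45, adjusted p = 0.899). Fstl1 differed by 1.22 ± 0.46 (adjusted p = 0.949). No gene passed edgeR's test, with 85 at an unadjusted p under 0.05; DESeq2 called 0, and the count was 1 without 3 day replicate 1. Against sham at 14 days the MI libraries (n = 2) had 386 ± 107 CPM of Cycs, the electron carrier cytochrome c, against 1978 in the single sham library (log2 -2.30, adjusted p = 0.563). The oxidative phosphorylation list was lower relative to other genes (camera adjusted p = 0.000411, and adjusted p = 0.92 with an estimated correlation), its median and mean fitted differences having opposite signs, while the median over all genes was 2.13. The sham total of 4765 counts leaves little to see: Lum had no count there and was at least 1.5-fold higher in MI. No gene passed edgeR's test, with 134 at an unadjusted p under 0.05 and the lone sham library assumed to vary like the others; DESeq2 called 1. Fstl1 averaged 2701 ± 479.6 against 1319 CPM (log2 1.025, adjusted p = 0.563). The median of 2.13 became 1.89 with RLE size factors.

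Bulk RFP-positive cells of neonates were compared with those 14 days after MI. Tnnt2, Igf2 and Mki67 rose in neonatal cells. Tnnt2, cardiac troponin T, averaged 10750 CPM against 22.1 ± 31.3 (SD, n = 2 each; log2 8.50 ± 0.68, adjusted p = 5.78e-09). Igf2 averaged 6362 ± 186 against 154 ± 202 CPM (log2 5.74 ± 0.68, adjusted p = 1.18e-06), and Mki67 416 ± 30.8 against 39.8 ± 40.7 (log2 3.75 ± 0.60, adjusted p = 4.93e-05). Mt2, a metal-binding stress protein, was lower, 15.4 ± 2.61 against 1084 ± 142 CPM (log2 -6.09 ± 0.40, adjusted p = 5.84e-10).

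Of 4680 genes 1419 passed edgeR's test, 667 higher and 752 lower in neonates, and DESeq2 called 500. The myoglobin gene Mb (log2 6.307), the imprinted H19 (6.122), Gm20300 (5.665) and the kinase gene Cdk2 (5.11) rose, and the spindle gene Tpx2 had 978 counts against 1, a ratio of 94.9 (95% interval 17 to 3750). The MHC class I gene H2-K1 (log2 -5.193), Crispld2 (-5.166), Col8a1 (-5.154), Serpinf1 (-4.816), Csrnp1 (-4.822) and Lars2 (-4.512) fell. Fstl1 averaged 3865 ± 730.7 against 2028 ± 301.8 CPM (log2 0.937, adjusted p = 0.0597). Of 21 mitotic cycle genes 20 rose, with Top2a at least 57.4-fold higher (camera adjusted p = 7.25e-16, and adjusted p = 0.216 with an estimated correlation). Of 14 DNA replication genes 8 rose, with Rrm2 at least 32.5-fold higher (camera adjusted p = 1.32e-06, and adjusted p = 0.216 with an estimated correlation). Of 20 oxidative phosphorylation genes 16 rose and 1 fell, with Cycs at log2 3.32 (camera adjusted p = 1.65e-07, and adjusted p = 0.216 with an estimated correlation), and 4 of 11 glycolysis genes rose and 1 fell (camera adjusted p = 0.0492, and adjusted p = 0.363 with an estimated correlation). Immediate early genes fell in 16 of 20, such as Nr4a1 (log2 -3.83, camera adjusted p = 8.87e-11, and adjusted p = 0.216 with an estimated correlation). Activated fibroblast genes fell in 10 of 18 with 1 up, such as Ctgf (log2 -4.15, camera adjusted p = 0.000249, and adjusted p = 0.254 with an estimated correlation). Resting fibroblast genes fell in 5 of 9 with 1 up, such as Gsn (log2 -4.04, camera adjusted p = 0.00882, and adjusted p = 0.216 with an estimated correlation). Scar late genes fell in 3 of 3 (camera adjusted p = 0.0245, and adjusted p = 0.216 with an estimated correlation) and MHC class II genes in 4 of 5, such as Cd74 (log2 -3.53, camera adjusted p = 0.00814, and adjusted p = 0.216 with an estimated correlation). Lipid and repair genes fell in 6 of 14 with 2 up (camera adjusted p = 0.0422, and adjusted p = 0.325 with an estimated correlation). Sarcomere genes, with 2 of 3 up and 1 down, and fetal growth genes, with 3 of 4 up and 1 down, did not pass as lists (camera adjusted p = 0.191 and 0.0556). The filter asked for 10 counts in at least 3 libraries, which a gene counted only in the 2 neonatal libraries cannot reach. These 2 results therefore cover only the few members measured and do not decide about the rest of the lists. Adjusted over the list alone, 21 mitotic cycle and 2 activated fibroblast genes rose, 18 immediate early genes fell and the other called lists had the same counts. Markers moved both ways, with 1 of 9 fibroblast markers up and 3 down, 3 of 11 endothelial markers down, and 3 of 11 macrophage markers up and 2 down. Of 6 smooth muscle markers 2 rose, of 4 pericyte markers 2 fell and of 3 neutrophil markers 1 rose. The labels name no surgery for the neonates, the barcode set differed between these groups and neonatal counts had no ceiling. Age, injury, library kind and cell mix therefore cannot be told apart. On the single-cell plates, cardiomyocytes made up 63.36% of the cells of the RFP neonatal letter. They made up 0%, 1.65% and 0% in MI infarct letters B, E and M. The marker counts above include no cardiomyocyte list, and the cell mix of the bulk libraries was not measured. The count was 575 without 14 day replicate 2, and 701 and 689 without neonatal replicates 1 and 2.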

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

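The tests of cardiomyocyte RNA, of the cell mix in bulk and of the run code were chosen after the result was seen.

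Fibroblasts of MI infarcts held more RNA of the activated fibroblast list than sham fibroblasts, with 1 of its 22 measured genes called. Over all genes tested 10 were called, 8 higher and 2 lower. The splits and the macrophage share below concern those 10 genes and the 8 higher ones, not the list. Only 10 splits of the 6 letters exist, too few for a share under 0.05; the real split, counted as 1 of 10, called 10 genes and the highest other split called 1. RNA from macrophages in the fibroblast sums stays open for part of the genes, since 25% of the 8 genes called higher were more abundant in the macrophages of the same CEL-Seq letters, above the 20% written beforehand as the bound against it. Chemistry cannot be told apart either: the list's median log2 difference was 0.84 within CEL-Seq2 (resampling the 22 genes, 0.37 to 1.76) and 1.91 within CEL-Seq (0.76 to 3.32), above the bound of 0.5 in both, but the lower interval crosses that bound and 1 side of each chemistry is a single letter. The infarct itself, the biological explanation the design names, remains open and was not separated from these.

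Sarcomere genes passed as higher in neonatal fibroblasts. In the RFP neonatal plate, 100.0% of 13 sarcomere genes had a fibroblast to cardiomyocyte ratio within 2-fold of the median ratio of 5.66% (range 3.30% to 10.26%), as RNA from 1 source gives. That is consistent with RNA from cardiomyocytes of the same plate, which held 185 of them among 292 cells. On the living neonatal plate, where 1 cardiomyocyte was found, the fibroblasts had 942.9 CPM of these genes against 7955.1. Expression by neonatal fibroblasts themselves was not tested apart from this and stays open for the remainder.

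Bulk RFP-positive cells changed between 3 and 14 days after MI. After correction for identifier collisions, 97.0% of the called genes stayed called with the same sign, more than the 90% written before this result. The correction itself was added after seeing the data. Few genes neared the ceiling, so the loss of most calls was hardly within reach. Counts above 128 were seen in 9 and 74 genes at 3 days and in 19 and 117 at 14 days. The calls thus hardly depended on the correction, which does not decide about the ceiling. More macrophages and fewer fibroblasts among the sorted cells at 3 days may account for part or all of it. Of the genes called higher, 89.1% were more abundant in macrophages than in fibroblasts of the single-cell plates. Of those called lower, 68.7% were more abundant in fibroblasts, short of a bound of 80% set after the result was seen. A change of mix need not reach that bound, since 4 of 4 endothelial markers also fell. The same shares among all tested genes were not taken, so these shares do not decide the question. Run code and time cannot be told apart, because 0 times had libraries under both codes. A change within the cell types stays open and was not tested.

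For sham against unoperated adult fibroblasts, the count was 0 genes, which each of the 56 splits reaches whatever the data, so the splits say nothing about chance. The highest other split, with letters P, R and W (1 sham and 2 adult letters) as 1 side, called 31, which points to some structure of the samples that was not tested.

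Among the 6 unoperated adult letters, letter Z stood apart from the others in 2 of 24 groups of values tested, where chance gives about 1 in 20. Its median was 5038 transcripts per cell, with the nearest letter at 2725, a gap of 0.641 of the range. Macrophages made up 35.86% of its cells, with the nearest letter at 5.56%, a gap of 0.845 of the range.

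Between the I/R and MI infarcts, which share the sham contrast, the resting fibroblast list differed in fibroblasts (camera adjusted p = 0.00352) and so did the capillary endothelium list (camera adjusted p = 0.00483), and neither passed with an estimated correlation. Between the 3 and 7 day bulk libraries, which share the 14 day contrast, the collagen and matrix list (camera adjusted p = 0.000727) and the immediate early list (0.00751) differed, and neither passed with an estimated correlation.

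On the living MI plate, which enters no test between groups, Myl7, the light chain of atrial myosin, was at 5303 CPM in cardiomyocytes and at 8.814 CPM in those of the RFP neonatal plate.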

How the results depend on the processing

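These alternatives were chosen after seeing the data: a minimum of 10 cells, Rn45s and 4 other abundant genes left out, bulk counts corrected for identifier collisions, the bulk sham library left out of the fit, the letters A, B, E and F without a block, the share minimum of 20 cells, and letter I against living adults or letter U against RFP adults. The minimum of 5 cells, used for the values reported, also replaced the planned 20 after cell numbers were seen and before any test. The other alternatives were planned. The cause of the changes below was not tested, except that fewer letters enter where cells or letters were left out. The alternatives other than replicates left out in turn gave 2490 gene values, some of them from fewer letters. Of these, 2290 kept their direction and side of the threshold, 178 lost the call, 9 gained it and 13 changed sign. Of 1271 gene values with a replicate left out, 155 lost the call, 1 gained it and 10 changed sign. Of 136 share values 121 kept both and 15 changed sign.

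Numbers of called genes moved as follows. For MI against sham fibroblasts (10) DESeq2 gave 45, filterByExpr 16, no count filter 109, cells of at least 2000 transcripts 4, no chemistry covariate 2, only the groups compared 1, cycling cells left out 1, Rn45s and 4 other abundant genes left out 14, and left-out replicates 0 to 18. For I/R against sham (0) no filter gave 44. For I/R against MI (0) DESeq2 gave 1, no filter 12, only the groups compared 1 and cycling cells left out 1. For infarct against remote area (0) no filter gave 8, only the groups compared 20, a replicate block over letters A, B, E and F 28, and the same letters without the block 25. For neonates against adults (223) no filter gave 406, letter I against living adults 43 and letter U against RFP adults 20, each changing both the neonatal letter and the adult group. For sham against adults (0) DESeq2 gave 2, no filter 22 and only the groups compared 4. For endothelial cells (0) no filter gave 1. For macrophages after MI (0) no filter gave 4, no chemistry covariate 45, only the groups compared 38, cycling cells left out 2, the planned 20 cells 183, 10 cells 12 and left-out replicates 0 to 43. For macrophages after I/R (2) DESeq2 gave 0, no filter 20, at least 2000 transcripts 5, no chemistry covariate 1, only the groups compared 0, cycling cells left out 16, the planned 20 cells 17, 10 cells 1 and left-out replicates 0 to 2. For bulk 3 against 14 days (439) DESeq2 gave 190, filterByExpr 836, no filter 896 and left-out replicates 266 to 421; for 7 against 14 days (552) these were 239, 1038, 1200 and 205 to 358. For 3 against 7 days (0) left-out replicates gave 0 to 1. For 14 day MI against sham (0) DESeq2 gave 1, filterByExpr 2 and no filter 12. For bulk neonates (1419) DESeq2 gave 500, no filter 2141 and left-out replicates 575 to 1164. Of 71 list calls, 10 passed with an estimated correlation. A block on replicate numbers in bulk gave 450, 586, 0, 0 and 1302 genes in the order of the report; numbers were not shown to pair samples, as differences of like-numbered replicates correlated across genes at 0.27, -0.02 and -0.05 in bulk and 0.07 in fibroblasts.

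These values changed sign. In fibroblasts, Fstl1 between I/R and MI (0.05) was -0.0138 with RLE, -0.0192 with DESeq2, -0.2961 with 10 cells and -0.0484 to 0.1824 with replicates left out, lowest without I/R replicate 2. Fstl1 between infarct and remote area (-0.11) was 0.099 without the chemistry covariate, 0.1755 with 10 cells and -0.2546 to 0.0241 with replicates left out, highest without remote replicate 1. With replicates left out, Mki67 ranged from -6.2771 to 1.0879 for I/R against sham (-4.22) and from -1.84 to 5.0241 for sham against adults (3.15), the change of sign being without sham replicate 3 in both. Top2a was -0.0967 with letter U against RFP adults (4.81 in neonates). In endothelial cells Mki67 (-0.77) was 0.7224 with 20 cells, 0.7268 with 10 and -10.2359 to 0.127 with replicates left out (highest without I/R replicate 1), and Fstl1 (0.67) was -0.0715 with 20 cells. In macrophages after MI Mki67 (0.62) was -1.4495 without the chemistry covariate, -1.9189 with 20 cells (adjusted p = 0.0179), -1.9108 with 10, and -1.918 to 0.9117 with replicates left out, below 0 without sham replicate 1 (-1.918) and MI replicate 2 (-0.0242). After I/R Mki67 (0.36) was -0.0457 with cycling cells left out, and Lyve1 (-4.20) ranged from -4.4609 to 0.2632, the latter without sham replicate 4. In bulk neonates Rtp4 (-1.73) and Ccl3 (-2.52) ranged from -2.3586 to 1.2206 and from -3.2177 to 5.9222, each highest without 14 day replicate 2. Among differences of shares in points, B lymphocytes (-0.15) were at 0.014 and 0.348 with 500 and 2000 transcripts and 0.231 in CEL-Seq2 letters, and smooth muscle (-0.55) at 1.139 in CEL-Seq2 letters and 6.713 with 20 cells per letter. Cardiomyocytes (0.23) were at -0.035 in CEL-Seq2 letters. With replicates left out smooth muscle ranged from -10.344 to 4.546, B lymphocytes from -0.431 to 0.402, cardiomyocytes from -0.014 to 0.436 and cycling fibroblasts (-10.03) from -16.7 to 3.3.

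The planned cycling test at 500 transcripts was not run, since thinning needs 1000, and the table of the whole series held the same bulk values and gave no alternative. CEL-Seq2 letters alone left too few letters for most fits. Letters of 5 to 18 fibroblasts, and a sham bulk library of 4765 counts, limit which genes could pass.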

Other observations

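Cardiomyocytes of the living MI plate and of the RFP neonatal plate, each a single letter of another age, expressed the sarcomere list at 88270 CPM (exact Poisson 95% interval 87330 to 89220; 92 cells) and 107400 CPM (107100 to 107600; 185 cells). All 92 cells of the MI plate were in cluster 12, and those of the neonatal plate in clusters 13 (130) and 19 (55). The top genes of cluster 12 included Myl7, of atrial myosin, Myl4 and Nppa. Atrial cells on the MI plate were therefore not told apart from age, injury or sort. Members of the list differed in both directions. Nppa, the atrial natriuretic peptide, was at 5031 CPM (4808 to 5262) on the MI plate against 367.3 (352.6 to 382.5), the light chain Myl4 at 3910 (3714 to 4115) against 22.19 (18.68 to 26.17) and the heavy chain Myh7 at 582.7 (508.4 to 664.8) against 278.1 (265.3 to 291.4). Tnni1, the slow skeletal troponin I, was at 1985 CPM (1951 to 2020) on the neonatal plate against 10.55 (2.874 to 27.0). Mki67 was at 227.9 CPM (216.3 to 239.9) on the neonatal plate and at 10.55 (2.874 to 27.0) on the MI plate; the former was sorted with the reporter and the latter without it, so these values are not comparable. The intervals cover counting error only.

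Sarcomere RNA was also counted in other cell classes of both plates. In the neonatal plate the list reached 7775.5 CPM in only 2 endothelial cells and 5732.2 in 5 macrophages. In the MI plate it was at 7516.1 CPM in 40 endothelial cells, 5362.3 in 19 macrophages and 4117.1 in 20 fibroblasts. On adult living plates J and K, fibroblasts had 789.5 and 252.7 CPM and endothelial cells 1629.9 and 1589.3.

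The remote areas enter only part of the comparisons. Of endothelial cells in the MI remote area 11 of 83 were cycling (13.25%, exact 95% interval 6.81 to 22.48), and in the sham remote area 2 of 51 (3.92%), from letter C alone, whose title points to the apex while its source name gives the remote area. Cluster 1 held 11 and 3 of these endothelial cells, so the doubt about its name applies here too. Of macrophages in the MI remote area 5 of 54 were cycling (9.26%). On the living MI plate 0 of 40 endothelial cells were cycling, which allows a share of up to 7.5%.

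In bulk, Mki67 itself was counted sparsely in the adult libraries of sorted RFP-positive cells, with 4 and 9 counts at 3 days, 3 and 40 at 7 days, 3 and 1 at 14 days and 1 after sham, and with 254 and 233 counts in the neonatal libraries.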
